A study of Caenorhabditis elegans with 4 samples.

How the data were processed

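ChIP-seq was performed on C. elegans fem-2(b245) young adults with 5 µg of affinity-purified antibody, after crosslinking of ground frozen worms for 20 minutes with EGS and a further 10 minutes with EGS and formaldehyde, per the labels' protocols. Of the 4 libraries, 2 were REC-8 immunoprecipitations and 2 were inputs. Peak lists of the ChIP libraries and a combined list were analysed, and the input libraries were not analysed here. Groups and replicate numbers came from the sample titles.

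Reads were aligned with BWA to ce10, per the submitters' processing notes, and the peaks are on WormBase WS220, per the file headers. The replicate lists name MACS as their source and the combined list names MACS v2, per the source column of the deposited files. The deposited score of each peak comes from the peak caller, and its scale is not given in the sources used here. The replicate scores start at 50 and the combined scores at 1.31, so scores were compared only among peaks of 1 list or between the replicate lists, never between a replicate and the combined list. Whether the inputs served as background, how the replicates were combined, the filters and the tool versions are not given in the sources used here. The combined list was treated as the authors' own value, with no n. A peak's calling depends on sequencing depth and on the fragment length assumed by the caller, and neither is given in these lists, so peak numbers and widths of the replicates may reflect them as well as binding.

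From the deposited starts and ends, the widths, midpoints and overlaps were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9. Coordinates are 1-based as in the files. Chromosome extents were taken as the largest peak end on each chromosome over the 3 lists, 100.3 Mb in all, since no WS220 sequence was used here. Mitochondrial peaks were left out of every comparison and are given separately. Peaks were shared when they overlapped by at least 1 bp. Chance overlap came from 100000 circular shifts of a list within each chromosome, which keep the widths and order of the peaks. The density on X was tested by rotating the positions 100000 times along the joined chromosomes, and the arms by an exact sign-flip test over the 6 chromosomes. Spacing was compared with 1000 uniform placements, in which simulated peaks could overlap, and the share of neighbours within 5 kb with 200 such placements. Medians and correlations were tested with 100000 permutations. The threshold was 0.05.

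These tests, the alternatives and the rule for named peaks were chosen before the data were examined. The rule took the 3 highest-scored combined peaks per chromosome among those in both replicates, the 5 widest peaks and the 3 densest windows of 100 kb. The alternatives were an overlap of at least 50% of the shorter peak, midpoints within 500 bp, the higher-scored 50% of each list, peaks within 500 bp merged, base pairs in place of peak numbers, the outer 2 of 4 equal parts of a chromosome against the inner 2, uniform placement, the combined list alone and each replicate left out. Each statistic was tested on simulated data. With independent lists of the replicates' sizes, 4% of 50 runs of the overlap test had p below 0.05, and 100% did when 50% of the peaks of one list were planted on the other. The rotation test had p below 0.05 in 4% of 50 runs with equal density, and in 100% with X at 50% of the autosomal density. Those simulated peaks were placed independently at a single autosomal density, so they lacked the clustering and autosomal density differences of the real lists. The correlation test had p below 0.05 in 10% of 20 uncorrelated runs. Ranges in the closing section cover 95% of 1000 resamplings of the peaks, taken as independent.

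Positions relative to genes, and lists of meiotic, germline, somatic and noncoding genes fixed beforehand, were planned only if an annotation of WS220 was given. The gene table at hand is on WBcel235, a different build, so peaks were not assigned to genes and those comparisons were not made.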

Results

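The binding of REC-8 along the chromosomes was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Caenorhabditis elegans. REC-8 is a meiotic kleisin subunit of cohesin, the ring complex that holds sister chromatids together. The worms were fem-2(b245) mutants, described as germline-bearing young adult hermaphrodites kept at 20 degrees Celsius, although the growth protocol speaks of gravid adults. The gene fem-2 encodes a protein phosphatase of the sex determination pathway that promotes male fates, including spermatogenesis in hermaphrodites. The series held 2 ChIP libraries made with a rabbit polyclonal antibody to REC-8 and 2 input libraries. The values analysed were 3 lists of peaks called by the authors, 1 for each ChIP replicate and 1 combined list. No read counts were used here, so the depth behind each peak is unknown and no interval or detection limit based on depth could be given. Nothing in the descriptions says that the replicates came from separate cultures, so differences between them may be technical. The p-values compare the lists with moved or permuted peaks, or with sign flips over chromosomes. None of them measures the spread between replicates.

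REC-8 peaks covered a small part of the nuclear genome in every list. Replicate 1 had 1961 peaks on the 6 nuclear chromosomes with a median width of 430 bp, which covered 1.22% of the chromosome extent. Replicate 2 had 2026 peaks with a median width of 1468 bp, covering 3.75%. The authors' combined list had 5889 nuclear peaks with a median width of 294 bp, covering 2.75%. The quartiles of the width were 274 and 623 bp in replicate 1, and 1181 and 1992 bp in replicate 2.

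The first comparison asked whether both immunoprecipitations marked the same places. Of the replicate 1 peaks, 1586 of 1961 (80.9%) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 1189 of 2026 (58.7%) overlapped a replicate 1 peak. Circular shifts of a list within each chromosome gave 5.21% and 4.24% by chance, so the overlaps were 15.5 and 13.9 times the chance level. None of 100000 shifts reached either value (one-sided permutation test, p = 1e-05 in both directions, the smallest that this number of shifts can give). Places shared one to one lay close together, a set that leaves out the 240 replicate 2 peaks overlapping 2 or more replicate 1 peaks. At these 948 peaks, the midpoints were a median of 54 bp apart, and 943 of the replicate 1 peaks lay wholly inside the replicate 2 peak. Wider replicate 2 peaks make such nesting more likely, with median widths here of 463 bp in replicate 1 and 1457.5 bp in replicate 2.

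Sharing rose with the peak score in both lists. With each list cut into 4 equal groups by score, 59.7% of peaks were shared in the lowest group of replicate 1, against 96.9% in the highest. The corresponding shares in replicate 2 were 25.6% and 98.2%. The scores themselves ran in parallel across the 948 pairs, with a Spearman rho of 0.70 and a Pearson r of 0.74. Each had a permutation p of 1e-05, the smallest possible, which 100000 permutations gave and which Benjamini-Hochberg adjustment over these 2 coefficients left at 1e-05. Without the 2 pairs farthest from the median replicate 1 score, r was 0.73. These correlations run across peaks, which are not independent replicates. Many high scores were tied, since 46 replicate 1 peaks and 82 replicate 2 peaks scored exactly 3100, and only 3 and 5 scored higher. Among the 909 pairs in which both scores were below 3100, rho was 0.66.

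**Figure D1:**
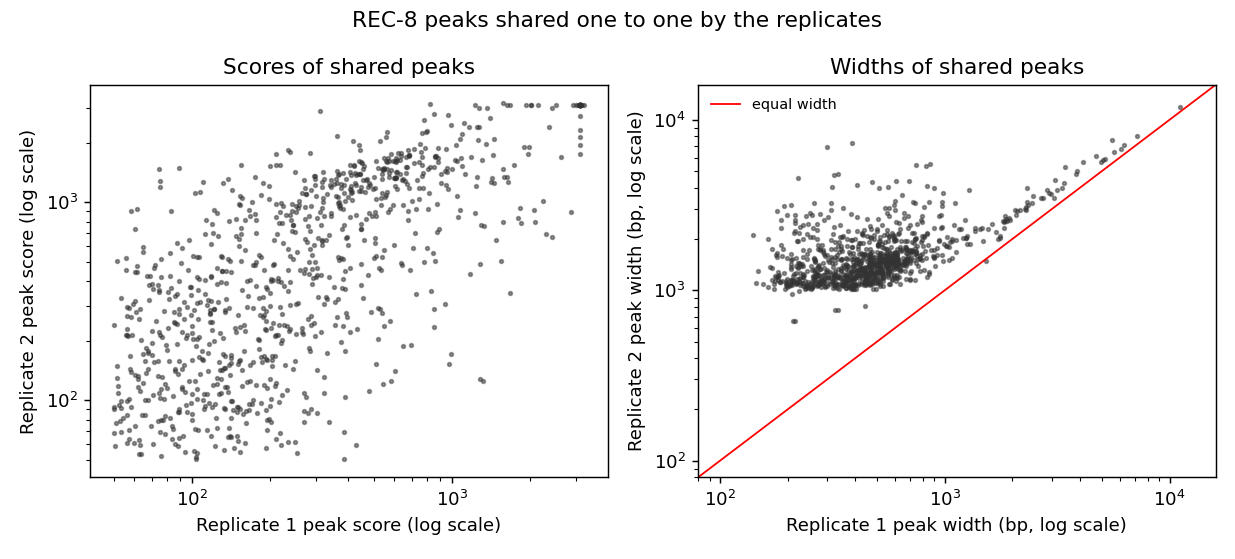
Each point is 1 of the 948 REC-8 peaks shared one to one by the replicates, with the replicate 1 value on the horizontal and the replicate 2 value on the vertical axis, on log scales, for the peak score (left, no unit) and the peak width in bp (right). Scores rose together (rho 0.70), and 947 of the 948 peaks were wider in replicate 2, above the line of equal width.

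The combined list was then set against the replicates. It held nearly every replicate peak, namely 97.1% of those of replicate 1 and 99.8% of those of replicate 2. Of its own 5889 peaks, 1360 (23.1%) overlapped a peak in both replicates, 1639 (27.8%) one in replicate 2 alone and 339 (5.76%) one in replicate 1 alone. The remaining 2551 (43.3%) overlapped none in either. With the higher-scored 50% of each list, 748 of 2944 combined peaks (25.4%) were in both and 53.9% in neither. Peaks found in both replicates had a median combined score of 48.9 and a median width of 698 bp, against 6.36 and 250 bp for all other combined peaks. Both differences had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. A wider peak has more room to overlap, and the combined list was made from the same study. Higher scores and widths among peaks in both replicates were therefore likely in advance. Neither these counts nor the permutation p-values are independent evidence for a peak.

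The X chromosome had the lowest peak density of the 6 nuclear chromosomes in all 3 lists. It carried 11.3 ± 1.64 peaks per Mb (SD, n = 2 replicates). Among the autosomes, chromosome III had 26.4 ± 2.57 peaks per Mb and chromosome I 25.2 ± 4.79. Chromosomes IV and II had 21.2 ± 0.525 and 21.1 ± 0.463, and chromosome V had 17.04 ± 1.45. The combined list gave 34.9 peaks per Mb on X and between 48.6 on V and 83.6 on III for the autosomes.

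The log2 ratio of X to the autosomes was -0.76 in replicate 1 and -1.15 in replicate 2, a mean of -0.96 ± 0.27 (SD, n = 2), or 0.516 times the autosomal density. Rotating the peak positions along the joined chromosomes gave a ratio as large in a fraction 0.016 of 100000 rotations (two-sided permutation p). All 153 windows of X length that were as extreme, of 10028 tested at 10 kb steps, covered at least 90.3% of X. Windows with no part of X had ratios between -0.27 and 0.53. The rotation p-value thus mainly counts rotations that returned nearly to X itself. It does not measure how often chance gives a chromosome so low. Measured as base pairs covered in place of peaks, the ratio was -0.81 ± 0.43 (SD, n = 2), with a permutation p of 0.052, which was not past the threshold. It was -0.50 in replicate 1 and -1.12 in replicate 2. With 6 chromosomes, chance alone would make X the lowest in 1 of 6 cases, so chromosomes taken as units could not decide this comparison.

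**Figure D2:**
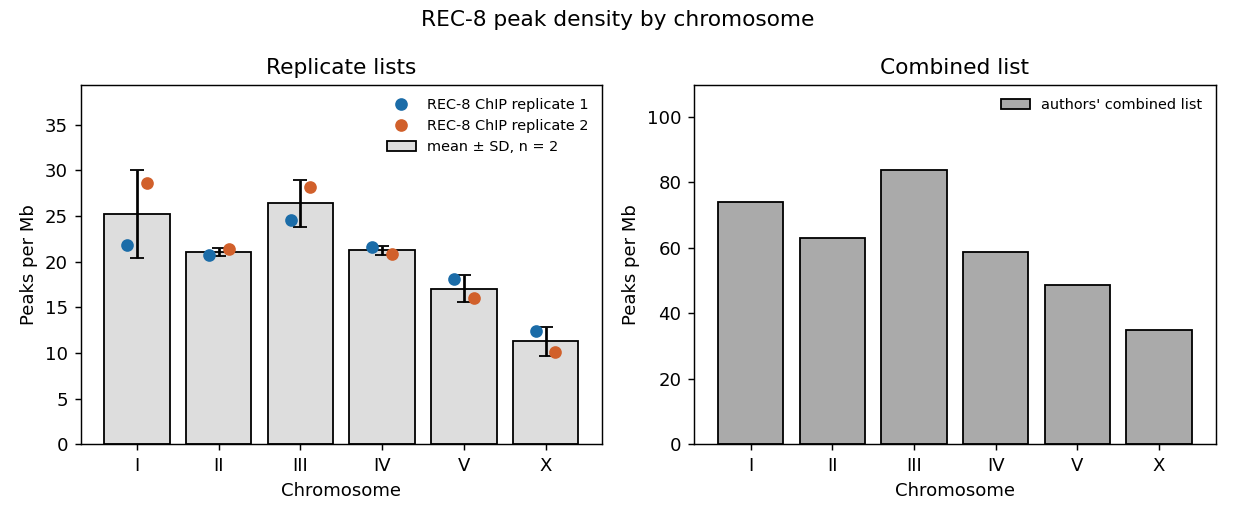
REC-8 peaks per Mb (vertical axis) on each nuclear chromosome (horizontal axis): on the left the mean of the replicate lists as bars with the SD (n = 2) and each replicate as a point, on the right the authors' combined list. X was lowest in every list, at 11.3 ± 1.64 peaks per Mb in the replicates and 34.9 in the combined list.

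Worm chromosomes have arms and centres that differ in recombination, and the peaks were compared between them. Each chromosome was cut into 3 equal parts. X had more peaks per Mb in its outer parts than in its middle part, by a log2 ratio of 0.77 in replicate 1, 0.75 in replicate 2 and 0.24 in the combined list. The autosomes had mean replicate ratios between -0.25 on chromosome I and 0.36 on chromosome IV. Over the 6 chromosomes the mean was 0.17 ± 0.35 (SD across chromosomes), with 4 of 6 positive, and it did not differ from 0 (exact sign-flip test, two-sided p = 0.34, where the smallest possible was 0.03125). In replicate 1 alone 4 of 6 were positive, and in replicate 2 alone 2 of 6. In the combined list the mean had the other sign, at -0.09, with 1 of 6 positive (exact p = 0.28). A difference between X and the autosomes was not tested, since 1 chromosome against 5 cannot reach the threshold in an exact test.

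**Figure D3:**
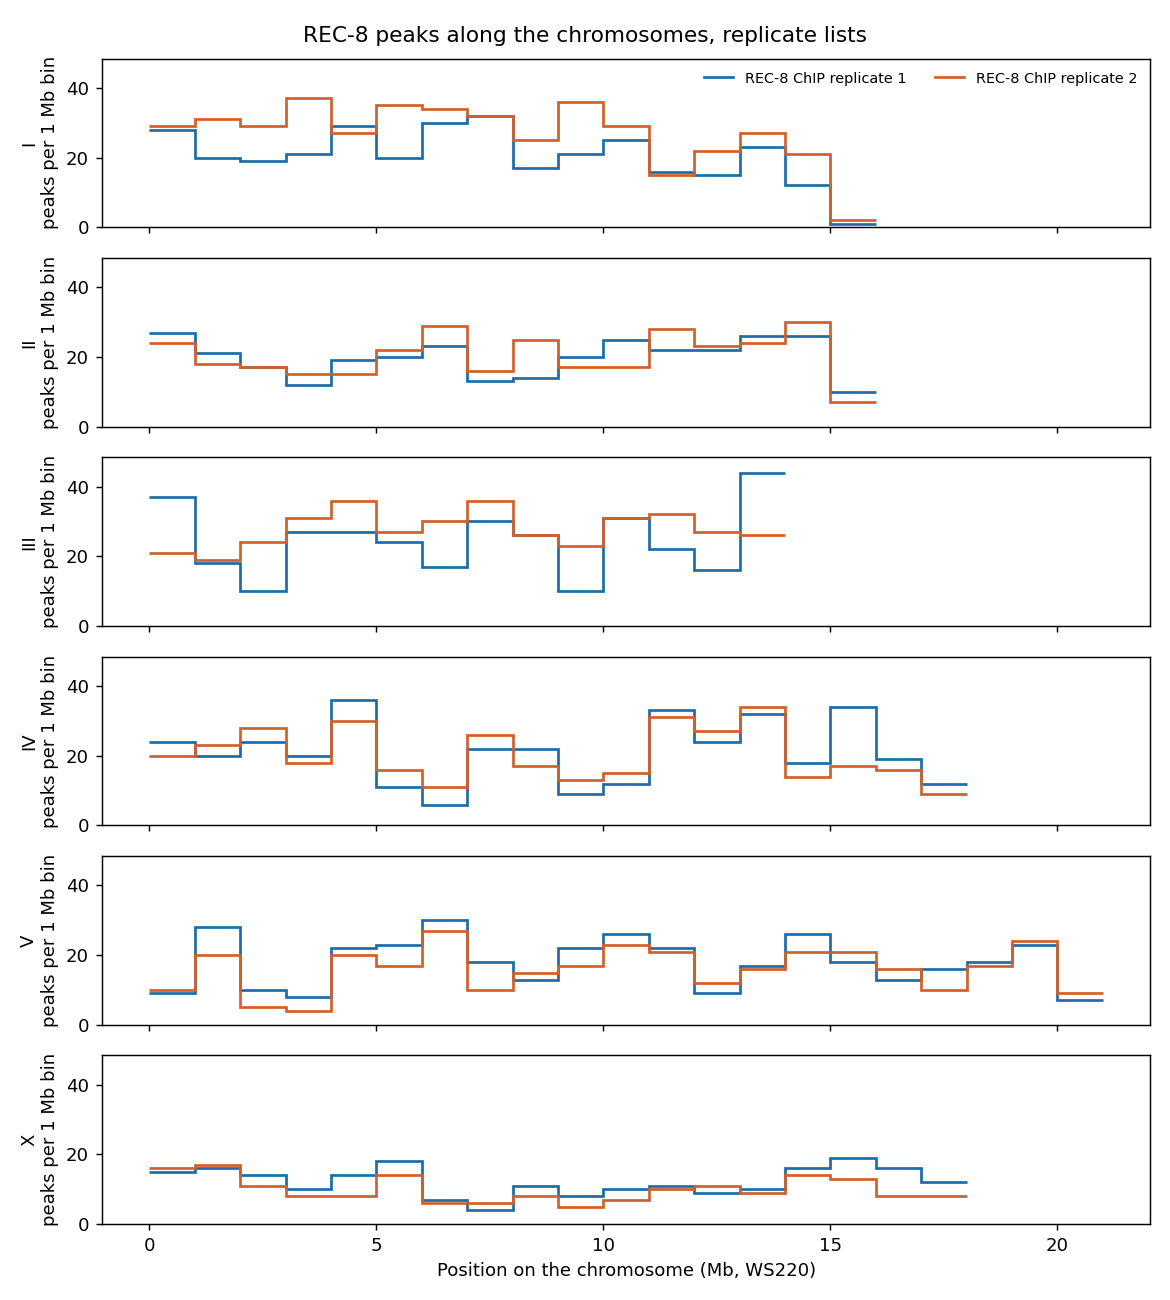
Number of REC-8 peaks per 1 Mb bin (vertical axis) along each nuclear chromosome (horizontal axis, Mb, WS220) in replicate 1 and replicate 2, drawn as step lines. The last bin of each chromosome is shorter than 1 Mb. The mean over X was 11.3 ± 1.64 peaks per Mb.

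Peaks were closer together than uniform placement would give. Neighbouring midpoints were a median of 22.8 kb apart in replicate 1 and 28.6 kb in replicate 2, against 34.4 and 32.0 kb for uniform placement, ratios of 0.663 and 0.895 and a mean log2 ratio of -0.38. In each replicate none of 1000 placements gave a spacing as short (one-sided permutation p = 0.001, the smallest possible). Neighbours within 5 kb made up 33.2% of replicate 1 neighbours and 12.2% of replicate 2 neighbours, where 200 uniform placements gave 9.66% and 10.5%. The mean log2 ratio was -0.60 in replicate 1 alone and -0.16 in replicate 2 alone. Merging peaks within 500 bp gave -0.13 (permutation p = 0.001). The ratio of replicate 1 moved from 0.663 to 0.899 with merging, and that of replicate 2 from 0.895 to 0.928. Much of the close spacing in replicate 1 thus lay among peaks within 500 bp of one another. The higher-scored 50% of each list gave -0.13 with 0.18 as the larger permutation p of the replicates, which did not pass.

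The 3 highest-scored combined peaks found in both replicates on each chromosome were named. All 18 had combined scores between 158 and 162, close to the highest score of the list, and their order within that range carries little information. On chromosome I (WS220) they lay at 487976 to 488818, 9668676 to 9669601 and 13609892 to 13615688. On chromosome II they lay at 4553914 to 4555907, 4851470 to 4852234 and 11345341 to 11346046. The peaks of chromosome III were at 1618607 to 1619553, 8043491 to 8044291 and 11110636 to 11111033. Those of chromosome IV were at 8466874 to 8468376, 9066038 to 9069271 and 12021419 to 12025676. Chromosome V had 1868398 to 1869059, 12291276 to 12292089 and 12343318 to 12344108. On X they were at 3099657 to 3100219, 9007133 to 9009139 and 11206657 to 11207344. The X peak at 9007133 had the highest score of the replicate 1 list, 3228, with 3100 in replicate 2. The narrowest of the 18 was the 398 bp peak at 11110636 on chromosome III, which scored 1125 in replicate 1 and 1385 in replicate 2.

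The 5 widest combined peaks were 6.73 to 11.7 kb wide, and 3 of them were split into several peaks in replicate 1. Their combined scores ran from 17.6 to 144, below those of the high-scored peaks named above. The widest spanned 11.7 kb at 321610 to 333329 on chromosome III, where replicate 2 had 1 peak of 12476 bp and replicate 1 had 17 separate peaks. An 11.1 kb domain at 15060230 to 15071359 lay at the right end of chromosome I, the end that carries the large ribosomal RNA gene array, and it was a single peak with a score of 3100 in both replicates. The combined score of this domain was 35.5, and the inputs, which would show any background over the array, were not analysed here. A 10.7 kb domain at 16929355 to 16940038 on X was 1 peak in replicate 2 and 4 peaks in replicate 1, of which one of 6667 bp scored 3100, as did the replicate 2 peak. An 8.26 kb domain at 7916788 to 7925044 on chromosome V was a single peak with a score of 3100 in both replicates. The fifth, of 6.73 kb at 13592286 to 13599014 on chromosome III, was split into 10 peaks in replicate 1 and was part of a 15405 bp peak in replicate 2, the widest of that list.

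Peaks were also crowded in a few 100 kb windows. The combined list averaged 5.86 peaks per window, and 34 of 1005 windows had none. The window from 7400001 to 7500000 on chromosome III held 54 combined peaks, 16 replicate 1 peaks and 2 replicate 2 peaks. The windows from 6000001 and from 19000001 on chromosome V held 26 and 25 combined peaks.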

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

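Peaks on the mitochondrial chromosome lay outside the comparisons, and their presence called for a closer look. The combined list had 4 of them, at 1 to 6723, 6770 to 10518, 10771 to 13063 and 13127 to 13275, with combined scores of 32.9, 33.5, 32.5 and 8.41. Replicate 1 had 1 mitochondrial peak, of 13376 bp from 2 to 13377, with a score of 3100, and replicate 2 had 0. REC-8 is a nuclear protein, and the input libraries, which would show the mitochondrial background, were not analysed here.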

How the results depend on the processing

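Of 41 alternative values for 9 results, 36 kept their direction and their side of the threshold, and for counts stayed within 1.5 times. One, the X ratio over peaks shared by the replicates, was added after the data were seen (-0.86, permutation p = 0.016). The number of combined peaks in both replicates fell from 1360 to 748 when only the higher-scored 50% of each list was used, by construction with fewer peaks, and ranged from 1699 to 2999 when one replicate was left out and overlap with the other alone was counted, the higher value without replicate 1. The X ratio moved to -0.81 in base pairs covered (permutation p = 0.052), and the spacing ratio to -0.13 (log2) in the higher-scored 50% of peaks, where the larger permutation p of the replicates was 0.18. For both the cause was not tested. The arm to centre ratio reversed to -0.088 in the combined list (the cause was not tested), was not past the threshold there or in its other 6 alternatives, and ranged from 0.10 to 0.23 with one replicate left out. With midpoints within 500 bp the shared part of replicate 1 dropped to 58.7% and that of replicate 2 to 53.2%, still above chance (permutation p = 1e-05). The comparisons with genes and gene lists were not run, since no WS220 annotation was used here. No paired analysis was possible because the input libraries that share replicate numbers with the ChIP libraries have no values here. Depth is unknown, so a peak missing from a list cannot be read as absence of REC-8.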

Other observations

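The tests of chromosome starts, of left-out autosomes, of the combined list's X ratio by score and of pairing-centre ends were chosen after the results they bear on had been seen, and so were the runs and gaps described next. In the combined list, chaining peaks with gaps of up to 5 kb gave a run of 52 peaks over 46.8 kb on chromosome III, from 7405431 to 7452205, with a median score of 4.33. Replicate 1 had 14 peaks in it and replicate 2 had 1. The next runs were 23 peaks on chromosome V from 6071111 to 6101085 and 21 peaks on chromosome II from 9807989 to 9824324, a run with 0 peaks in either replicate. In replicate 2 the longest stretch without a peak was 594 kb on X, from 9744294 to 10338497. On chromosome I the longest gaps of the replicates nearly coincided, from 12149813 to 12507726 in replicate 1 and from 12150320 to 12507088 in replicate 2. On the other 5 chromosomes they lay apart, and the longest gap of the combined list on chromosome I was shorter, 181 kb from 12286623 to 12467157, so that list had peaks inside the stretch.

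All 6 nuclear chromosomes had a peak within their first 500 bp in all 3 lists. The first peak of X scored 832 in replicate 1 and 355 in replicate 2, and that of chromosome I 1410 and 951. Circular shifts of replicate 1 gave a mean of 0.126 such chromosomes and at most 3, so placement by chance is argued against (one-sided permutation p = 1e-05, the smallest possible). It stays open whether REC-8 was enriched there or whether reads of telomere repeats, which sit at chromosome ends, piled up, since the inputs were not analysed here. The far ends were not tested, because the chromosome extents were themselves taken from the last peaks. The last peak of X ended at 17610641 in replicate 1, 17611129 in replicate 2 and 17718897 in the combined list. On chromosome I it ended at 15071351, 15071786 and 15072444 in the same order. No biological explanation was tested.

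Peaks were wider in replicate 2 at 947 of 948 shared places. A stronger signal in replicate 2 that widens strong peaks predicted a smaller width difference at weak peaks. The median difference was instead 1012 bp in the lowest of 4 equal groups by replicate 1 score and 868 bp in the highest. That is a ratio of 1.17 (range 1.08 to 1.23 over resampled peaks). It cannot decide the question, because the groups were formed by replicate 1 score, not replicate 2 signal. The replicate 1 width that was subtracted also rose, from a median of 250 bp in the lowest group to 713 bp in the highest. A fixed extension of every peak, such as a longer fragment or shift length during calling, is another candidate explanation. It was left undecided by a Spearman correlation of the width difference with the score of -0.22, which lay between the bounds set beforehand (0.2 and 0.3 in size). The labels name no biological difference between the replicates, and whether they came from separate cultures is not said.

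The low density on X may rest in part on weak peaks that missed the score limit there, since in the replicates the log2 ratio was -0.69 in the higher-scored and -1.28 in the lower-scored 50% of peaks, a difference of 0.59 (0.45 in replicate 1 and 0.74 in replicate 2), above the bound of 0.5 set beforehand for the mean. The combined list had 2551 of 5889 peaks that overlapped none in either replicate. Its X ratio over all peaks was -0.87, against a mean of -0.96 in the replicates, so this longer list was still low on X. The order of the score groups was opposite in that list, -1.002 in the higher-scored and -0.75 in the lower-scored 50% of peaks. That difference of -0.25 (range -0.48 to -0.01 over resampled peaks) argues against lost weak peaks for that list. In 4 equal groups from low to high score the combined ratios were -0.94, -0.63, -0.97 and -0.96, so the difference came mainly from the second group, while those of replicate 1 rose at every step (-1.02, -0.98, -0.73 and -0.39) and those of replicate 2 did not (-1.28, -1.88, -0.88 and -0.76). A single peak-rich autosome is also argued against, since the ratio was at most -0.89 with each autosome left out in turn (-0.72 and -1.05 as the highest of each replicate). Lower read coverage of X and a biological difference of X chromatin both stay open and untested.

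Pairing centres, the sites near one end of each worm chromosome where homologs pair in meiosis, offered a hypothesis of more REC-8 peaks in the part that holds it than in the opposite part, with each chromosome cut into 3 equal parts. The centre was assumed at the right end of chromosomes I, III and V and at the left end of II, IV and X. These ends are not given in the sources used here and were not checked, so the values below depend on them. The end taken for chromosome III in particular may be wrong. With the opposite end its ratio would change sign, and the mean, the count above 0 and the p-value would change too. The mean log2 ratio over the 6 chromosomes was -0.082 ± 0.27 (SD), with 4 of 6 above 0 (exact sign-flip test, two-sided p = 0.5). It was -0.13 with 2 of 6 above 0 in replicate 1 alone, and -0.033 with 4 of 6 in replicate 2 alone. With 6 chromosomes that differ this much, and with assumed ends, the test left the hypothesis undecided. With the ends as assumed, the ratio ranged from -0.45 on chromosome II to 0.18 on chromosome III.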
